A study of Homo sapiens with 42 samples.

How the data were processed

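Strand-specific mRNA sequencing libraries of the multiple myeloma cell lines MM.1S and INA-6 were compared, 42 libraries in 14 groups of 3. Groups were cells without or with IL-6 for 24 hours, and Cas9-expressing cells given by lentivirus a guide RNA that targets EGFP (control), ELL2, HNRNPL, POU2AF1 or SRSF1, selected in puromycin for 2 days and kept with IL-6. The labels call the sgRNA cells knockdown cells. A time with IL-6 is not given on every INA-6 label. RNA was purified by silica column and treated with DNase. Libraries came from 1 of 2 sequencing providers, and which provider made which library is not given in the sources used here, so a provider batch could not be tested.

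The submitters' notes give alignment to GRCh38 with STAR 2.7.10b and handling with SAMtools 1.19.2. The splicing caller and its annotation release are not given in the sources used here. The authors' deposited tables, 1 for each of 8 comparisons, hold percent spliced in (PSI, in percent, 0 to 100) of each of the 3 libraries per group, the number of libraries with a value, and the difference of mean PSI in points. The differences were checked against the listed PSI values and matched to 0.01 points in all but 5 events. Within a group the libraries carry no replicate number. No read counts per event are listed, so the depth per library and the precision of a single PSI value are unknown, and the spread between libraries is the only measure of precision used.

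The deposited column headed as a Benjamini-Hochberg FDR holds an unadjusted p-value: recomputing Welch's two-sided test from the listed PSI gave the same value, within 1%, in 100% of the events with a value. It is treated here as an unadjusted p-value. The plan written before the data were examined had taken that column as adjusted, and its threshold of 0.05 with at least 10 points was kept. The tables for sgSRSF1 and sgHNRNPL list all events (58062 and 57895 with a p-value), and the other 6 list only events with p under 0.05, with further events without a p-value in the INA-6 tables. For these 6 tables the number of events was assumed to be 58062, and INA-6 gene list tests were not made because the measured genes are unknown. For list tests in MM.1S the measured genes were taken from the complete tables.

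In the INA-6 tables for sgPOU2AF1 and sgELL2 the headers of the value columns say MM.1S while the table names and the other headers say INA-6. Mean PSI of their sgEGFP groups correlated across events at 0.981 and 0.982 with INA-6 cells with IL-6, and at 0.928 and 0.939 with MM.1S cells with IL-6. They were taken as INA-6. The sgEGFP values were identical in 99.9% of the events shared by these INA-6 tables and in 99% of those shared by the sgSRSF1 and sgHNRNPL tables, so each pair has the same controls. MM.1S sgPOU2AF1 and sgELL2 have separate sgEGFP groups.

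An event was called at p under 0.05 and an absolute difference of at least 10 points. Direction splits were tested by exact binomial tests with Benjamini-Hochberg adjustment over 72 tests (9 event types in 8 comparisons), event types in the complete tables also by Fisher's exact test against events not called. The same-direction share of events called in both of 2 comparisons was tested by exact binomial tests adjusted over 12 pairs. As a test from single libraries, limma 3.58.1 in R 4.3.3 was fitted to logit PSI clipped to 1 and 99%, for events that varied after clipping (50136 for sgSRSF1 and 49610 for sgHNRNPL), and called at adjusted p under 0.05 and at least 10 points. In the 6 tables of selected events its adjustment covers selected events only. Differences between the cell lines were tested by the interaction term of the same model over the events listed in both tables. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

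The rules were tested on simulated data with the spread of the complete tables and 50 changed events at each of 4 sizes. The deposited rule called 210 and 265 unchanged events for sgSRSF1 and sgHNRNPL and recovered 40 and 42% of changes of 10 points, 94 and 88% of 20, 100 and 88% of 30 and 98 and 100% of 40. The limma rule called 4 and 5 unchanged events and recovered 0 and 2%, 22 and 20%, 42 and 36%, and 54 and 56%. Only 200 events were changed in each simulation. The adjustment is stricter where few events change, so the limma shares may be too low for sgSRSF1, where limma called 2058 events. For comparisons with the same controls, 50 simulations with no change gave the sharing that common controls alone produce.

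Coordinates are 1-based on GRCh38. Exons of single exon skipping events matched exons of GENCODE release 29 exactly in 82.6 to 94.9% per table and retained introns matched in 81.2 to 92.7%, and under 1% matched after a shift by 1 base. Coding, UTR and intron labels come from that release. The coordinates are those listed for the target of each event. For exon and intron events this is the segment whose inclusion PSI measures. For some alternative splice site events the listed span holds other exons, so it need not be the segment kept. For events with several skipped exons the coordinates are of the exon listed.

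The genes named were set by a rule made before the data were examined: the targeted genes in every comparison; the 8 genes with the largest increase and the 8 with the largest decrease among called events, with 1 event per gene and no overlap between the groups; up to 3 genes per gene list and comparison; and up to 5 per pair of comparisons. The report gives part of the genes this rule names, a part chosen after their values were seen. List members given by name alone fall outside the rule and were chosen in the same way. A few results are not reported here because their items are withheld. A read minimum in that rule could not be applied, and genes without a symbol were left out. The 17 gene lists were SR proteins, hnRNP proteins, core spliceosome and its regulators, transcription elongation, B cell and plasma cell genes, IL-6 and JAK-STAT signalling, apoptosis, MYC and cell cycle, unfolded protein response and secretion, nonsense-mediated decay and RNA turnover, DNA damage response, published SRSF1-responsive events, published HNRNPL-responsive events, RNA polymerase II termination and polyadenylation, chromatin regulators, T and NK cell markers, and stromal and myeloid markers. Lists were tested by Fisher's exact test of genes with a called event, adjusted over 80 tests. A gene with more events has more chances of a call, so 10000 random lists matched on events per gene gave a second p-value.

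Alternatives tried were a stricter p, 20 points, genes in place of events, other clipping, untransformed PSI, no minimum difference in the limma test, leaving out each library, 1 event per gene, matching by gene and event type, and, chosen after seeing the data, Benjamini-Hochberg adjustment of the deposited p, retained introns left out, no minimum difference for events shared by 2 comparisons, no overlap between the groups, and events with values in all 6 libraries. Gene expression was not analysed here, since the tables hold splicing values only.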

Results

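Alternative splicing was measured by strand-specific mRNA sequencing in MM.1S and INA-6, established human cell lines grown from multiple myeloma, a cancer of antibody-secreting plasma cells. The 42 libraries formed 14 groups of 3 libraries. In both cell lines, cells kept without interleukin-6 (IL-6), a growth factor for plasma cells, were set against cells given IL-6 for 24 hours. In 6 further comparisons, Cas9-expressing cells with a guide RNA against POU2AF1, ELL2, SRSF1 or HNRNPL were set against cells with a guide RNA against EGFP (sgEGFP), all with IL-6. POU2AF1 is a B-cell transcriptional coactivator, ELL2 is an RNA polymerase II elongation factor, and SRSF1 and HNRNPL are RNA-binding regulators of splicing. SRSF1 and HNRNPL were targeted in MM.1S only. Each of the 8 comparisons has a table of splicing events with the percent spliced in (PSI) of every library. PSI is the share of transcripts that keep the exon or intron of the event, or use its splice site. For some alternative splice sites the coordinates named span other exons, so they need not be the segment kept. Differences are in points of PSI, treated minus control. A gene named for 1 event may have further called events in either direction. Read numbers per event and per library are not given in the tables, so the depth is unknown. Groups are set side by side as mean PSI ± SD, the control first and the treated group next (SD, n = 3 libraries each unless another n is given). That the 3 libraries of a group came from separate cultures is not stated, so p-values of single events measure only the spread between these libraries, which may be technical. The exact binomial and Fisher's exact tests count events or genes as separate units and measure no spread between libraries. Events can shift together in a library, so these p-values do not say whether a split would recur in other libraries.

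An event was called where the p-value of the authors' deposited table was under 0.05 and PSI differed by at least 10 points. That p-value is not adjusted for the number of events, so part of each count is chance. Of the 58062 events of the sgSRSF1 table, a number assumed also for the 6 tables that list selected events, 5% are 2903. Simulated events with no change had p under 0.05 less often than that, 2064 with the spread of the sgSRSF1 table and 2036 with that of sgHNRNPL. With the 10 points, the rule called 210 and 265 of them. The counts of called events were 805 for IL-6 in MM.1S, 578 for IL-6 in INA-6, 425 and 736 for sgPOU2AF1 in MM.1S and INA-6, 310 and 365 for sgELL2 in MM.1S and INA-6, 3337 for sgSRSF1 and 1047 for sgHNRNPL. In all called events the libraries of the groups compared did not overlap, which chance gives for 10% of unselected events with 3 libraries against 3 but which the choice of events by p and size all but fixes, so it adds no evidence. After Benjamini-Hochberg adjustment of the deposited p, 178 of the called sgSRSF1 events stayed under 0.05, and 0 did in the other 7 comparisons. Events with unadjusted p under 0.05 numbered 9503 for sgSRSF1, 4241 for sgHNRNPL, 5776 and 4729 for IL-6 in MM.1S and INA-6, 4151 and 7256 for sgPOU2AF1, and 2823 and 3595 for sgELL2. The adjusted limma test on logit PSI called 2058 events for sgSRSF1 and 116 for sgHNRNPL. In the other 6 tables, which list only events already under 0.05 (and some without a p), limma called 800 and 568 for IL-6 in MM.1S and INA-6, 420 and 734 for sgPOU2AF1, and 306 and 361 for sgELL2. Those counts rest on that selection.

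**Figure D1:**
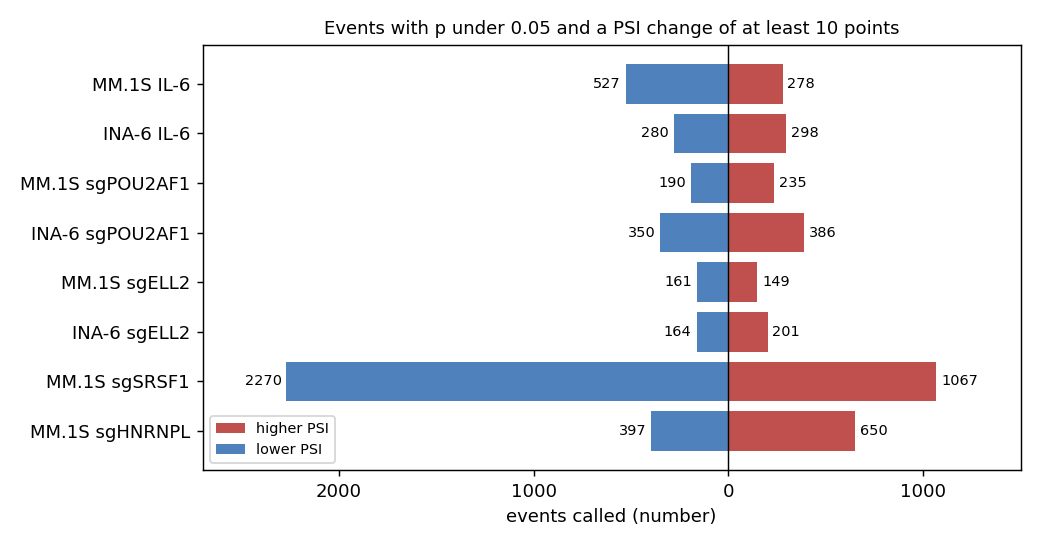
Number of called events (p under 0.05 in the authors' deposited table and a PSI change of at least 10 points) in the 8 comparisons, higher PSI to the right in red and lower PSI to the left in blue, with each count printed at its bar. With sgSRSF1 2270 events fell and 1067 rose, and with sgHNRNPL 650 rose and 397 fell.

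The targeted genes themselves were examined in every comparison where their events were listed. With sgELL2, ELL2 exons were skipped in both cell lines. A 164-nt exon at chromosome 5:95913771-95913934, listed in exon-run events whose outer ends differ between the cell lines, went from 91.2% ± 7.6 to 61.2% ± 3.7 in MM.1S and from 94.5% ± 1.7 to 59.6% ± 1.8 in INA-6. A further exon event at chromosome 5:95906523-95906782 went from 84.4% ± 0.56 to 70.4% ± 5.5 in MM.1S and from 91.4% ± 2.2 to 68.8% ± 0.81 in INA-6. An alternative 5' splice site at chromosome 5:95919424-95943002 rose from 0.613% ± 0.23 to 13.8% ± 1.5 in MM.1S and from 0.0808% ± 0.081 to 15.9% ± 0.84 in INA-6. That span holds the ELL2 exon at chromosome 5:95919424-95919545, which fell in other events of both lines. The rise may therefore not be a change apart from exon skipping. With sgPOU2AF1, inclusion of a 43-nt coding exon of POU2AF1 at chromosome 11:111357795-111357837 fell from 98.8% ± 0.076 to 79.5% ± 2.1 in MM.1S. In INA-6 the same exon went from 99.5% ± 0.082 to 91% ± 0.52, a shift under 10 points. With sgSRSF1, the SRSF1 event named here, a retained 3' UTR interval at chromosome 17:58003719-58004922, went from 51.4% ± 1.3 to 49.1% ± 1.8 (limma adjusted p = 0.653). With sgHNRNPL, a retained HNRNPL interval at chromosome 19:38836781-38837383 went from 0.114% ± 0.056 to 0.348% ± 0.11, a shift under 10 points. PSI does not measure abundance, so the loss of SRSF1 and HNRNPL was not checked by these values.

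**Figure D2:**
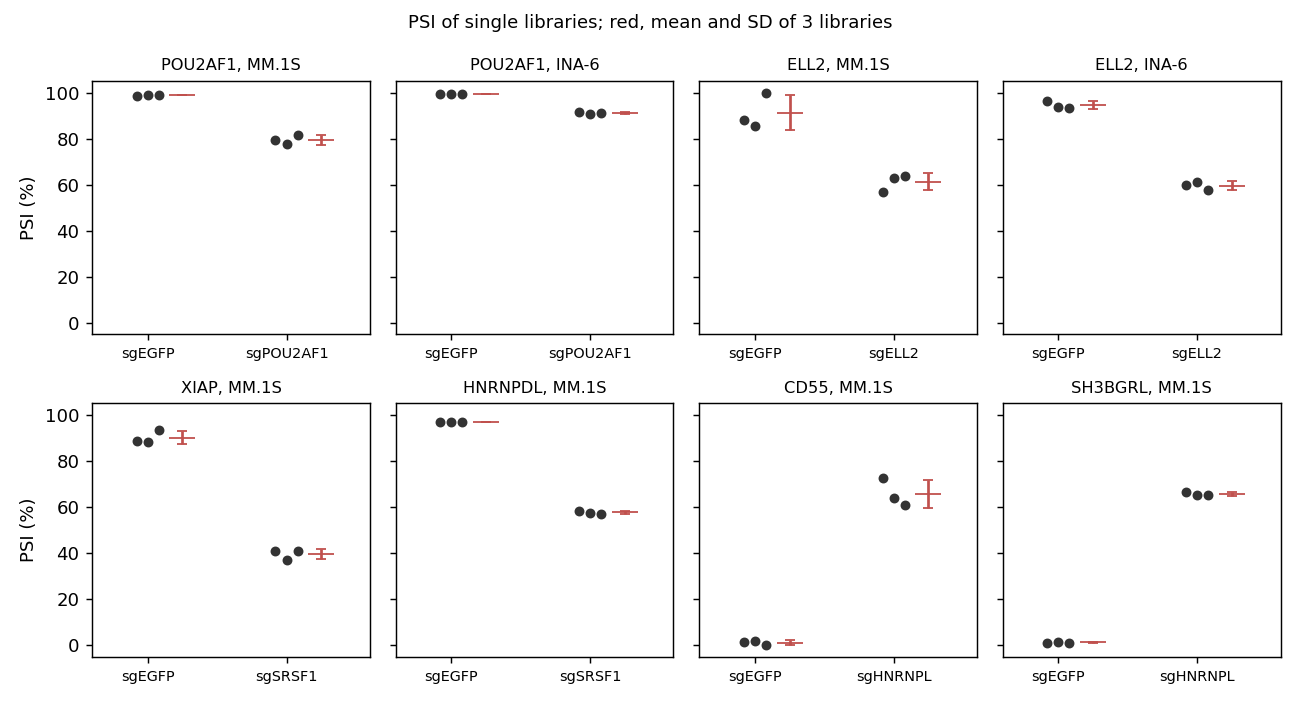
PSI in percent of single libraries (black points) for 8 events of 6 genes in sgEGFP cells and in cells with the guide RNA named on the axis, with the mean and SD of 3 libraries in red. The POU2AF1 and ELL2 exons are lower in each targeted library than in each sgEGFP library, XIAP and HNRNPDL exons are lower with sgSRSF1, and the CD55 and SH3BGRL splice sites rise from near 0 with sgHNRNPL.

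With IL-6 in MM.1S, called exons were skipped more often than they were included. Inclusion of a 130-nt exon of ITGA6, a laminin receptor subunit, fell from 74% ± 1.1 to 46.6% ± 1.4 at chromosome 2:172501772-172501901. Inclusion of a 90-nt exon of SREBF1, a transcription factor of lipid synthesis, fell from 66.1% ± 2.5 to 36.8% ± 6.6 at chromosome 17:17823518-17823607, and an 18-nt coding exon of the cytoskeletal linker DST fell from 76.6% ± 6.9 to 46.9% ± 3.2. The exon-run event of XIAP, an inhibitor of caspases, fell from 89.6% ± 2.9 to 64.5% ± 4.0 (SD, n = 2 and 3) at chromosome X:123885631-123886539. The kinase gene CLK1, whose product phosphorylates SR proteins, kept a 91-nt coding exon more often, from 55.4% ± 2.1 to 70.9% ± 2.9.

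Of the 805 called events in 589 genes, 278 rose and 527 fell, so 34.5% rose (exact 95% interval 31.2 to 37.9%). Without the 10 points the split over all event types was nearer to even, 2737 up and 3039 down at p under 0.05. The lean of exons stayed, with single exons at 579 up and 1255 down and exon runs at 205 and 440. Retained introns outside overlapping regions went the other way, with 621 up and 366 down. Events of one gene are not independent. Single skipped exons were included more in 69 events and less in 220 (exact binomial adjusted p = 3.72e-18 over 72 such tests), and runs of several skipped exons more in 18 and less in 115 (adjusted p = 3.1e-17). Alternative 3' splice sites leaned the other way, with 46 up and 25 down (adjusted p = 0.0453). Exons tagged as targets of nonsense-mediated decay were higher in 16 called events and lower in 40 (exact binomial adjusted p = 0.00491 against an even split), while the other called events, which lean the same way, rose in 262 and fell in 487. Among the largest increases were RACGAP1, a cytokinesis regulator (32.6% ± 4.5 to 67.4% ± 11.2, SD, n = 2 and 3) and TBC1D1 (33.5% ± 4.1 to 67.9% ± 1.6). CBFA2T2 (20.5% ± 4.9 to 53.9% ± 4.6), CRTC1 (17.2% ± 5.9 to 47.8% ± 5.0) and ANKS6 (20.5% ± 5.4 to 50.3% ± 4.6) rose as well. Among the largest decreases were CALHM2 (58.9% ± 8.2 to 18.6% ± 9.7) and LTBP4 (74.2% ± 2.9 to 39.3% ± 12.3). OAZ3 (55.1% ± 11.1 to 25.9% ± 10.7), the tyrosine kinase gene TEC (79.2% ± 2.7 to 50.7% ± 4.1) and the cytokine gene IL15 (55.1% ± 11.4 to 27.4% ± 12.6) followed.

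Among apoptosis genes, 5 of 28 measured members had a called event, against 5.8% of genes outside the list (Fisher's exact test, unadjusted p = 0.0214, adjusted p = 0.572). They were XIAP, the initiator caspase genes CASP9 (89.5% ± 5.3 to 71.5% ± 4.2) and CASP10 (78% ± 2.2 to 65% ± 0.26), BMF, and the cell death gene BCL2L11 (74.3% ± 4.5 to 86.6% ± 5.0). Of 57 core spliceosome genes and regulators 4 were called: CLK1, LUC7L, SF1 (86.7% ± 3.8 to 75.4% ± 2.7) and PRPF40B. A retained PRPF40B interval at chromosome 12:49642979-49643222 fell from 24.5% ± 3.7 to 5.74% ± 5.1, and it overlaps FMNL3 on the opposite strand, where an overlapping interval fell from 23.7% ± 1.9 to 3.17% ± 5.5. Of 41 cell cycle genes 3 were called. FOXM1, a transcription factor of mitotic genes, went both ways, with an exon up from 24.6% ± 2.1 to 40% ± 2.0 and the exon at chromosome 12:2865355-2865399 down (-13.9 points). The phosphatase gene CDC25C went down from 76.8% ± 3.1 to 61.3% ± 6.5 and CDK2 down from 91.5% ± 1.4 to 81.4% ± 2.1. Of 26 B cell and plasma cell genes 3 were called: the TACI receptor gene TNFRSF13B (63.5% ± 1.0 to 51.8% ± 0.62), IKZF3 (91.9% ± 0.8 to 79.1% ± 1.8) and MAF (14.4% ± 1.6 to 26.5% ± 1.6). Decay and turnover genes gave 3 of 28, among them SNHG1 (53.6% ± 3.0 to 31.2% ± 1.4) and UPF3A. Secretory pathway genes gave 2 of 35, the ER quality control genes EDEM2 (81.1% ± 5.2 to 66.5% ± 4.3) and UGGT1 (27.4% ± 1.2 to 12.9% ± 2.0). DNA damage genes gave ATRIP and RECQL5 among 43 measured, chromatin regulators gave HDAC7 (27.7% ± 1.7 to 12.9% ± 1.4) and KMT2E among 41, and CCNT2 was the elongation gene called among 26. HNRNPA2B1 was the hnRNP gene called among 26, and 0 of 13 SR protein genes were called. Of genes with published SRSF1-responsive events 3 of 20 were called, and of those with HNRNPL-responsive events CASP9 alone of 14.

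IL-6 in INA-6 gave 578 called events in 448 genes, 298 up and 280 down (exact binomial p = 0.48). Without the 10 points more rose, 2775 up and 1954 down at p under 0.05, with single exons at 774 and 514. Among the largest increases was that at an alternative 5' splice site of TET1, a 5-methylcytosine dioxygenase (43.5% ± 5.0 to 85.6% ± 17.1, SD, n = 2 and 3 at chromosome 10:68574253-68600769). Another was in the kinase gene NLK (20% ± 0 to 61% ± 7.6, SD, n = 2 and 3 at chromosome 17:28043332-28046831). ATP2A3, an ER calcium pump gene, rose at a 13-nt coding segment from 17.3% ± 6.2 to 52.6% ± 8.0, and BRD9, a chromatin remodelling subunit gene, rose from 19.7% ± 16.1 to 56.8% ± 9.6 (SD, n = 3 and 2). A 68-nt coding exon of MDM4, an inhibitor of p53, fell from 71.6% ± 13.3 to 38.2% ± 8.9 at chromosome 1:204537430-204537497. PSI fell in CDK14 (64.9% ± 3.1 to 36.9% ± 1.8), PPP1R9A (88.9% ± 9.7 to 61% ± 8.9) and PPIP5K1 (61.5% ± 2.7 to 33.9% ± 4.8). It also fell in STXBP6 (50.1% ± 4.2 to 22.8% ± 1.4), ZNF584 (50.8% ± 5.9 to 15.5% ± 12.2, SD, n = 2 and 3) and the long non-coding RNA FIRRE (74% ± 6.8 to 43.4% ± 7.7, SD, n = 3 and 2).

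Alternative 5' splice sites rose in 55 called events and fell in 32 (exact binomial adjusted p = 0.0458), while single exons rose in 108 and fell in 91 (adjusted p = 0.486). Cell cycle genes with calls were MDM4 and cyclin D3, CCND3, where a 216-nt exon rose from 58.2% ± 3.5 to 74.8% ± 3.6. Called B cell genes were PTPRC, which encodes CD45 (29.6% ± 0.099 to 40.6% ± 0.23), and BACH2 (8.23% ± 3.1 to 20.1% ± 5.4). DNA repair genes were LIG4 (51.7% ± 9.6 to 80.7% ± 8.9), FANCM (35.4% ± 7.2 to 14.2% ± 5.0) and FANCL (45.8% ± 0.49 to 27.7% ± 2.4, SD, n = 2 and 3). Other list members were LUC7L3 (31.3% ± 1.3 to 49.5% ± 6.5) and AFF4 (100% ± 0 to 87.9% ± 3.3). STRADA (71.2% ± 4.3 to 54.4% ± 3.1), SEC24B and CASP10 (67.7% ± 4.2 to 55.1% ± 1.9) were called too. The number of list members measured in INA-6 is not known, because events over the p threshold are not listed.

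The response to IL-6 overlapped in direction between the cell lines. Of 38 events called in both, 29 moved the same way (76.3%, exact 95% interval 59.8 to 88.6%, exact binomial adjusted p = 0.00332 over 12 pairs of comparisons). A 75-nt coding exon of the motor protein gene MYO5A at chromosome 15:52337810-52337884 fell from 48.4% ± 2.6 to 24.1% ± 3.4 in MM.1S and from 67.6% ± 1.2 to 46.8% ± 5.1 in INA-6. A 3' UTR interval of ARSG at chromosome 17:68421237-68421684 was retained more, from 70.2% ± 2.6 to 95.1% ± 2.1 and from 60% ± 2.9 to 82.1% ± 0.66. AMZ2 rose from 16.4% ± 3.8 to 48.1% ± 10.1 in MM.1S and from 43.9% ± 6.8 to 61.4% ± 0.61 in INA-6, and PNISR fell from 68.7% ± 3.9 to 51.3% ± 2.5 and from 79.5% ± 3.8 to 63.3% ± 3.9. The PRPF40B interval fell in INA-6 from 69.1% ± 4.5 to 39.2% ± 2.9 as in MM.1S. A 24-nt exon of UGGT1 fell in INA-6 from 39.1% ± 6.4 to 24% ± 1.8. A 111-nt coding exon of HDAC7 at chromosome 12:47795906-47796016 went against this pattern, falling in MM.1S and rising in INA-6 from 31.7% ± 1.1 to 45% ± 1.1.

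Targeting POU2AF1 in MM.1S gave 425 called events in 329 genes, 235 up and 190 down (exact binomial p = 0.0327). The potassium channel gene KCNN3 rose at an alternative 5' splice site from 12.7% ± 3.2 to 54.4% ± 10.1. ATP8A1 (42.3% ± 4.5 to 80% ± 9.3, SD, n = 2 and 3) and ACTL6A (25.5% ± 14.2 to 62.7% ± 14.4) rose, as did ASAP2 (19.6% ± 5.7 to 54.9% ± 11.7), ZNF419 (35.6% ± 5.7 to 64.4% ± 10.3) and ODF2L (15.8% ± 3.7 to 44.3% ± 6.0). HSD11B1L fell from 65.8% ± 6.0 to 24% ± 3.7 (SD, n = 2 each) and the nuclear envelope gene SYNE2 from 76.5% ± 10.8 to 41.1% ± 15.7. The IgM receptor gene FCMR fell from 51.1% ± 13.2 to 16.3% ± 7.9, RGS3 from 46% ± 5.8 to 14% ± 7.5 and RTF2 from 57.2% ± 1.5 to 25.9% ± 0.75. Runs of skipped exons were included more in 46 events and less in 23 (adjusted p = 0.022), and alternative 3' splice sites rose in 12 and fell in 32 (adjusted p = 0.012). Called retained introns rose in 17 events and fell in 24 outside overlapping regions (adjusted p = 0.613) and rose in 38 and fell in 20 within them (adjusted p = 0.0614). Of introns listed with p under 0.05 at any size, 773 rose and 260 fell outside such regions and 331 rose and 140 fell within them.

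B cell and plasma cell genes had 3 called members of 26 measured, against 3.06% of other genes (Fisher's exact test, unadjusted p = 0.0448, adjusted p = 0.583). That test counts POU2AF1, the targeted gene itself, and was not run without it. Besides POU2AF1 the called members were MAF (27.5% ± 3.6 to 15.4% ± 2.4) and TNFRSF13B (66.7% ± 0 to 51% ± 1.7), whose control libraries all hold the same value. Called splicing factor genes were PTBP2 (42.7% ± 9.8 to 68% ± 2.3) among hnRNP genes and LUC7L, PRPF40B and U2AF1L4 among 57 core genes and regulators. A 102-nt coding exon of KMT2A rose from 44.3% ± 4.0 to 58% ± 6.0, and CASP10 rose from 68.3% ± 2.0 to 79.3% ± 2.5. NUMB, a Notch inhibitor gene, fell at a 5' UTR segment from 27.6% ± 7.1 to 7.67% ± 5.2 and TJP1 fell from 42.4% ± 5.7 to 28.4% ± 2.9. SEC24B fell from 37.1% ± 4.9 to 24.5% ± 5.4, SNHG1 rose from 58.9% ± 1.3 to 69.1% ± 0.94 and PAPOLG rose from 82.4% ± 4.7 to 92.5% ± 3.2.

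Targeting POU2AF1 in INA-6 gave 736 called events in 548 genes, 386 up and 350 down (exact binomial p = 0.197), and retained introns rose. Introns with higher retention numbered 78 and with lower retention 20 (adjusted p = 2.3e-08), and for introns in overlapping regions the counts were 89 and 28 (adjusted p = 9.84e-08). Of the introns listed with p under 0.05, 93.9% rose outside overlapping regions and 86.7% within them, and the median change of each set, falls included, was 1.22 points. Runs of skipped exons went the other way from MM.1S, with 31 up and 57 down (adjusted p = 0.022), a difference between the lines that was not itself tested, and alternative 5' splice sites rose in 27 and fell in 54 (adjusted p = 0.012). Among the largest decreases was that at an alternative 5' splice site of the nucleoporin gene NUP210, from 59.8% ± 0.49 to 10.3% ± 0.94 at chromosome 3:13325165-13325795. CAMK1D (64.5% ± 9.3 to 27.1% ± 14), ABCC4 (71.6% ± 5.1 to 38.9% ± 2.5), the integrin gene ITGB4 (92.3% ± 1.7 to 60.1% ± 4.2) and the chaperone gene HSP90AA1 (61.2% ± 3.4 to 29.1% ± 5.8, SD, n = 2 and 3) fell. EBAG9 (56.6% ± 5.9 to 95.9% ± 3.6), the inhibitory receptor gene LAIR1 (33.7% ± 7.0 to 67.9% ± 4.7), VPS13D (9.37% ± 7.4 to 37.9% ± 7.7) and LPAR2 (31.6% ± 2.7 to 59.8% ± 8.1) rose.

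In the IL-6 signalling list, a 90-nt exon of STAT5A rose from 62.4% ± 7.6 to 82% ± 0.97 and an intron of the Janus kinase gene TYK2 from 13.2% ± 2.2 to 23.6% ± 1.3. Splicing factor genes fell at the events called, HNRNPH1 from 32% ± 3.5 to 16.2% ± 4.0 and HNRNPU from 72.1% ± 2.7 to 60.3% ± 5.1. DDX5 fell from 63.4% ± 4.4 to 45.1% ± 6.0, LUC7L3 from 48.2% ± 3.4 to 36.5% ± 5.3 and CLK4 from 22.9% ± 4.2 to 11.5% ± 1.0. DNA repair genes went both ways, with FANCA up from 55.8% ± 1.5 to 67.8% ± 5.1, and RAD51D from 61.5% ± 2.6 to 47.8% ± 3.2 and BRCA1 from 79.2% ± 4.5 to 68.9% ± 2.5 down. CDK12 fell from 22.7% ± 4.1 to 12.2% ± 1.2, BIN1 fell from 73.2% ± 4.7 to 57.6% ± 7.2, KMT2D rose from 83.3% ± 3.3 to 97.3% ± 4.6 and SMG1 rose from 15.5% ± 5.2 to 30.8% ± 3.5. Between the cell lines, 15 of 18 events called in both moved the same way (83.3%, exact 95% interval 58.6 to 96.4%, exact binomial adjusted p = 0.0117). With 1 event per gene it was 78.6% of 14 (adjusted p = 0.0833), past the threshold no longer. They included a 142-nt UTR exon of CDK14 (62.3% ± 5.7 to 86.1% ± 1.9 in MM.1S and 31.6% ± 2.7 to 56.8% ± 6.2 in INA-6) and SPEN (33.4% ± 3.6 to 16.2% ± 4.4 and 60.4% ± 7.3 to 30.2% ± 12.2). Also shared were the sialyltransferase gene ST3GAL6 (38.2% ± 4.3 to 23.6% ± 1.2 and 45.4% ± 3.1 to 27.4% ± 2.4) and IGFLR1 (79.7% ± 2.0 to 61.7% ± 7.5 and 52% ± 2.1 to 38.1% ± 1.6). PRDM15 went opposite ways, from 55.5% ± 5.3 to 37.4% ± 2.3 in MM.1S and from 45.6% ± 3.9 to 62% ± 1.7 in INA-6.

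Events called both with IL-6 and with POU2AF1 targeted in the presence of IL-6 mostly moved in opposite directions. They were few, 48 in MM.1S and 42 in INA-6, beside 805 and 578 events called with IL-6. In MM.1S 44 of 48 events called in both comparisons were opposite (91.7%, exact 95% interval 80 to 97.7%, exact binomial adjusted p = 9.08e-09). In INA-6 38 of 42 were opposite (90.5%, interval 77.4 to 97.3%, adjusted p = 2.26e-07). With no minimum difference, 12.7% of 754 shared events in MM.1S and 26.7% of 815 in INA-6 moved the same way. In INA-6 the NUP210 splice site rose with IL-6 from 15% ± 1.5 to 38% ± 1.7 and fell with sgPOU2AF1. NLK fell with sgPOU2AF1 from 37.2% ± 3.1 to 7.2% ± 6.5, and the kinase gene MAP2K6 went from 58.4% ± 2.1 to 78.2% ± 1.3 with IL-6 and from 66.7% ± 0.95 to 43.2% ± 5.7 with sgPOU2AF1. PTPN18 went from 51% ± 5.3 to 67.3% ± 2.5 with IL-6 and from 69.4% ± 2.2 to 53.2% ± 3.3 with sgPOU2AF1, and the CDK14 exon from 59.9% ± 3.8 to 33.4% ± 2.1 with IL-6. In MM.1S KIFC3 fell with IL-6 from 71.4% ± 7.7 to 44.1% ± 9.8 and rose with sgPOU2AF1 from 48.8% ± 1.7 to 69.3% ± 6.5 (SD, n = 2 and 3). SAMD12 fell from 94.7% ± 4.6 to 76.9% ± 6.6 and rose from 68.7% ± 3.5 to 88.6% ± 3.9, and FMNL3 rose with sgPOU2AF1 from 6.48% ± 2.3 to 26.3% ± 1.1. TTBK2 fell in both, from 81.7% ± 9.3 to 58.9% ± 8.4 with IL-6 and from 80.8% ± 10.9 to 53.6% ± 5.1 (SD, n = 3 and 2) with sgPOU2AF1, and MVB12A rose in both. Of the 3 events that differed by at least 20 points in both comparisons of MM.1S, 66.7% moved the same way, but 2 of the 3 are the TTBK2 site listed with 2 coordinate pairs and the same values, and the third is KIFC3, so 1 site went each way.

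**Figure D3:**
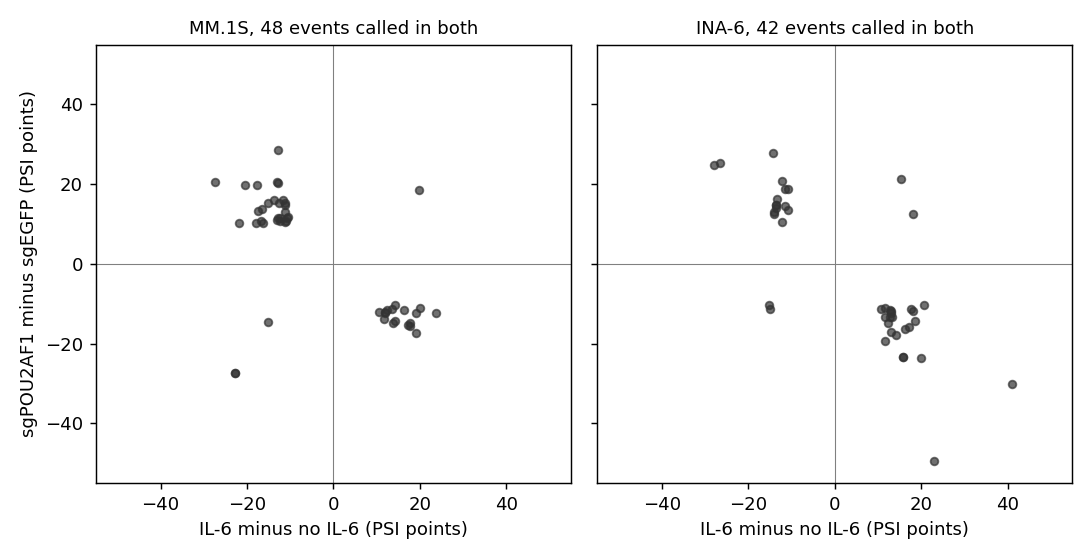
PSI change with IL-6 (horizontal axis, points) against PSI change with sgPOU2AF1 (vertical axis, points) for each event called in both comparisons, MM.1S on the left (48 events) and INA-6 on the right (42 events). The opposite quadrants hold 44 of 48 events in MM.1S and 38 of 42 in INA-6.

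Targeting ELL2 gave the fewest called events, 310 in 256 genes in MM.1S and 365 in 294 genes in INA-6. The numbers with p under 0.05 were 2823 and 3595, beside 2064 unchanged events in the simulation on the sgSRSF1 table. At 5% of the assumed 58062 events, chance gives 2903, which is more than the number in MM.1S. With the 10 points the rule called 210 and 265 unchanged events in the simulations for sgSRSF1 and sgHNRNPL. Much of the sgELL2 counts may therefore be chance. In MM.1S 149 rose and 161 fell (exact binomial p = 0.532), and in INA-6 201 rose and 164 fell (p = 0.0594). In INA-6 called introns in overlapping regions rose in 27 events and fell in 10 (exact binomial adjusted p = 0.022). In MM.1S ELL2 itself was among the largest decreases, and MAP2K6 (7.91% ± 7.7 to 54.8% ± 14), the kinase gene DYRK1B (23.1% ± 5.4 to 56% ± 1.9), MAPRE3 (44.7% ± 9.5 to 72% ± 4.7) and ACAD10 (68.9% ± 4.1 to 96.1% ± 6.8) rose. TRIM52 (70.4% ± 11.6 to 41.5% ± 7.4) fell. XIAP rose from 66.9% ± 4.5 to 86.8% ± 8.7, and MGA, a gene of the MYC network, had a coding exon that fell from 74.9% ± 6.3 to 55.4% ± 1.4. DNA damage genes were called in 4 of 43 measured members (ATM, ATR, RAD52 and RECQL5; Fisher's exact test, unadjusted p = 0.0212, adjusted p = 0.572), with ATR from 45.5% ± 6.7 to 59.7% ± 3.4 and ATM from 52.2% ± 3.4 to 40.7% ± 4.3. A 360-nt coding segment of FN1, on the list of stromal and myeloid markers, rose from 55.1% ± 5.0 to 73.6% ± 5.7. Others were CLK4 (65.9% ± 2.2 to 76.3% ± 2.4), IKZF3 (17.4% ± 3.7 to 27.7% ± 3.2) and CDC25C (76.7% ± 3.1 to 64.4% ± 4.3). CENPE (71.5% ± 4.2 to 61.2% ± 4.3), NUMB (18.3% ± 2.4 to 6.93% ± 3.9), KDM6A (61.7% ± 4.5 to 48.7% ± 2.6) and KMT2C (44.4% ± 0.12 to 33.1% ± 0.76) fell.

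In INA-6 with sgELL2, LCAT (51.3% ± 8.3 to 95% ± 4.4, SD, n = 2 and 3), CCDC180 (50.9% ± 10.8 to 84.1% ± 14), GLUD1 (64.7% ± 12.1 to 94% ± 7.9) and C5orf34 (70% ± 2.6 to 98.4% ± 2.7, SD, n = 2 and 3) rose. ISCU, a gene of iron-sulphur cluster assembly, fell from 67.5% ± 3.2 to 39.5% ± 8.0 (SD, n = 2 and 3), as did BOD1L1 (44.1% ± 12.8 to 14.7% ± 5.6, SD, n = 3 and 2). ZNF517 (85.9% ± 12.8 to 51% ± 3.3, SD, n = 3 and 2) and ANKRD42 (93.1% ± 6.4 to 65.2% ± 13.1) fell as well. The apoptosis genes BCL2L1 (33.4% ± 3.0 to 50% ± 7.1) and BBC3 (39.3% ± 6.1 to 53.2% ± 4.0) rose. Splicing factor genes went both ways, with CELF1 up from 20.4% ± 4.1 to 32.8% ± 1.2 and DDX39A from 26.4% ± 7.3 to 4.15% ± 3.9 and DDX5 from 63.4% ± 4.4 to 50% ± 2.1 down. NELFA, a pausing factor gene, rose from 35.2% ± 3.8 to 48.5% ± 3.4, SEC16B fell from 73% ± 0.85 to 60.3% ± 3.8, and an intron of ZAP70, on the T and NK cell list, was retained from 8.27% ± 4.7 to 20.5% ± 3.2. All 8 events called in both cell lines moved the same way (exact binomial adjusted p = 0.0117, and 0.0536 with 1 event per gene). These tests count ELL2, the gene targeted in both lines, and were not run without it. They therefore do not show by themselves a response shared by other genes. Besides an ELL2 exon, the 8 events included C16orf86 (62.1% ± 3.5 to 79% ± 1.4, SD, n = 3 and 2 in MM.1S and 49.6% ± 7.0 to 66.8% ± 4.5, SD, n = 3 and 2 in INA-6) and IGFLR1 (85.1% ± 7.1 to 64.1% ± 7.3 and 52% ± 2.1 to 39.7% ± 1.5). GATAD2A fell (60.7% ± 3.8 to 49% ± 5.5 and 45% ± 5.0 to 31.8% ± 0.31) and SKP2 rose (48.9% ± 4.3 to 61.8% ± 4.6 and 56% ± 2.4 to 67.5% ± 2.0).

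Against IL-6, all 11 events called with sgELL2 in INA-6 were opposite (adjusted p = 0.00234). The same IL-6 comparison and the same sgEGFP libraries gave the opposite directions with sgPOU2AF1 in INA-6, so the 2 results are not independent. Examples are RUFY2 (95.6% ± 4.3 to 83.4% ± 2.4 with IL-6 and 72.7% ± 1.7 to 92.1% ± 3.8 with sgELL2) and MYL6 (8.09% ± 2.4 to 22.3% ± 6.3 and 30% ± 8.1 to 12.7% ± 5.0). Counted by gene and event type, 25% of 16 moved the same way (adjusted p = 0.102). In MM.1S 9 of 13 events called with IL-6 and sgELL2 moved the same way (69.2%, exact binomial adjusted p = 0.32). Between sgPOU2AF1 and sgELL2, all 6 shared events in MM.1S moved the same way (exact binomial adjusted p = 0.0417, and 0.0833 with 1 event per gene), including MIB2 (55.5% ± 6.8 to 39.2% ± 2.8 and 44.6% ± 5.7 to 30.5% ± 5.7) and SLC12A7. In INA-6 all 69 shared events did, such as LCOR (58.5% ± 5.9 to 31.8% ± 10.1 and 58.5% ± 5.9 to 35.4% ± 4.9) and PALD1. Both comparisons use the same sgEGFP libraries, and unchanged groups simulated against shared controls also gave 100%. That simulation had on average only 0.42 events called in both, beside the 69 observed, and took its spread from selected events. Its 100% rests on few events, so how far shared controls account for the 69 is not known.

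Targeting SRSF1 changed splicing most widely, with 1067 called events up and 2270 down in 1879 genes, so 32% rose (exact 95% interval 30.4 to 33.6%). A 171-nt exon of HNRNPDL at chromosome 4:82426463-82426633 fell from 96.8% ± 0.046 to 57.7% ± 0.57 (limma adjusted p = 0.00154). The XIAP exon run at chromosome X:123885631-123886539 fell from 90.2% ± 3.0 to 39.7% ± 2.3 (limma adjusted p = 0.00615). A 142-nt exon of CASP8 fell from 96.4% ± 0.78 to 67.2% ± 1.0 (limma adjusted p = 0.00358), and a 231-nt exon of the splicing regulator gene RBM10 from 78.5% ± 2.2 to 48.2% ± 3.0 (limma adjusted p = 0.00854). The HDAC7 exon that IL-6 lowered in MM.1S rose from 24.9% ± 2.6 to 54% ± 0.86 (limma adjusted p = 0.00848). The limma test called 590 events up and 1468 down, and 748 to 999 with any 1 library left out.

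Single exons were included more in 304 events and less in 817 (exact binomial adjusted p = 3.64e-53), and runs of exons more in 120 and less in 572 (adjusted p = 1.48e-69). Retained introns went the other way, 118 up and 35 down (adjusted p = 1.47e-10). Against the events not called, single exons (odds ratio 1.87, Fisher's exact test adjusted p = 1.74e-55) and exon runs (1.82, adjusted p = 2.64e-36) were over-represented and retained introns under-represented (0.2, adjusted p = 4.52e-132). The last rests in part on the 10 points. Without them 989 retained introns rose and 282 fell at p under 0.05, with a median change of 1.52 points, beside -4.89 for single exons. Exons tagged for nonsense-mediated decay rose in 74 events and fell in 195 (adjusted p = 7.75e-13 against an even split), while the other called events, which lean the same way, rose in 993 and fell in 2075. Among the largest increases were the ubiquitin ligase scaffold gene CUL7 (25.9% ± 3.6 to 78.9% ± 3.9), DST (36.3% ± 6.6 to 88.7% ± 2.7) and PEAK1 (39% ± 4.9 to 85.5% ± 13). KIF9 (37.9% ± 8.4 to 81.2% ± 10) and PARP11 (35.1% ± 1.6 to 79.9% ± 11.7) also rose. Among the largest decreases were SEPTIN7 (91.5% ± 5.9 to 12.7% ± 21.9, limma adjusted p = 0.0533), the non-coding RNA LINC01138 (90.5% ± 0.64 to 21% ± 1.1, SD, n = 2 and 3) and XRRA1 (93.4% ± 1.9 to 28.3% ± 12.6). Others were ANKDD1A (84.8% ± 14.8 to 21.9% ± 2.2), HEMK1 (82.8% ± 7.2 to 25.1% ± 0.81), MSH5 (82.3% ± 5.5 to 25.1% ± 12.7) and DOK3 (74.4% ± 7.4 to 18.1% ± 3.3). Of the genes given with PSI but no limma value for sgSRSF1, PEAK1, PARP11, ANKDD1A, HNRNPA2B1, IKZF1 and NUMB had named events that did not pass the adjusted limma test, and the others passed.

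Of 26 hnRNP genes 8 had a called event, with HNRNPD from 43.4% ± 4.7 to 22.7% ± 4.0 and an intronic exon of HNRNPA2B1 tagged for decay from 33.6% ± 1.6 to 66.3% ± 8.3 (SD, n = 2 and 3). Of 178 tested hnRNP gene events 13 passed limma over all events and 15 adjusted over the list alone. Of 57 core spliceosome genes and regulators 17 were called, among them RBM23 (46.3% ± 1.6 to 19.9% ± 0.52) and LUC7L (27% ± 5.8 to 54.5% ± 9.3), with 18 events past limma over all and 19 adjusted over the list alone. Of 13 SR protein genes 2 were called, SRSF5 (22.2% ± 1.1 to 9.68% ± 1.5) and SRSF8 (64.4% ± 0.32 to 45.5% ± 2.8), with 3 events past limma over all and 3 adjusted over the list alone. Apoptosis genes gave 7 of 28, including BCL2L12 (89% ± 3.4 to 62.8% ± 5.3). The list had 16 events over all and 17 adjusted over the list alone. Cell cycle genes gave 9 of 40, with RBL1 down from 90.4% ± 0.55 to 45.5% ± 14.5, CCNE1 down from 89.5% ± 5.2 to 61.3% ± 5.4 and CDC25C up from 66.6% ± 4.4 to 94.8% ± 0.6. The list had 9 events past limma over all and 11 adjusted over the list alone.

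In the IL-6 signalling list 4 of 31 genes were called. Among them were the receptor gene IL6R (86.6% ± 1.3 to 66.8% ± 5.1), GAB1 (15.1% ± 0.69 to 34.2% ± 2.6) and STAT3, with 3 events past limma over all and 3 adjusted over the list alone. B cell and plasma cell genes gave 5 of 25, including SLAMF7 (49.8% ± 0.77 to 70.3% ± 1.4), MEF2C (83.4% ± 0.28 to 69% ± 0.63) and IKZF1 (68.4% ± 4.1 to 52% ± 6.8), with 8 events over all and 9 adjusted over the list alone. Transcription elongation genes gave 5 of 26, and ELL2 was among them. An ELL2 segment at chromosome 5:95932632-95932663 fell from 13% ± 2.1 to 1.24% ± 0.53, and the exon at chromosome 5:95898240-95898810 fell from 99.9% ± 0.26 to 87.3% ± 4.0. CDK13 fell from 41.9% ± 0.9 to 16.9% ± 1.1, with 5 events past limma over all and 5 adjusted over the list alone. Secretory pathway genes gave 5 of 35, with the ER co-chaperone gene DNAJB9 from 98.2% ± 0.18 to 62.3% ± 0.12, and 4 events over all and 4 adjusted over the list alone. DNA damage genes gave 4 of 43, with BRCA1 from 87.3% ± 4.8 to 48.6% ± 2.8 and CHEK2 from 86.5% ± 2.7 to 68.9% ± 2.3, and 8 events both over all and adjusted over the list alone. Decay and turnover genes gave 8 of 28, with SNHG12 from 51.8% ± 3.1 to 22.5% ± 2.4 and UPF3A from 46.1% ± 4.6 to 70.6% ± 0.84. The exon junction gene MAGOH went from 70.2% ± 1.1 to 47.9% ± 3.3, and the list had 14 events both over all and adjusted over the list alone. Chromatin regulators gave 12 of 41, with KMT2D from 95.8% ± 7.2 to 44.4% ± 12.9 and BPTF from 43.2% ± 1.5 to 71% ± 8.5 and 9 events past limma both over all and adjusted over the list alone. Termination and polyadenylation genes gave 3 of 23, FIP1L1 from 32.8% ± 1.2 to 64.7% ± 2.3, RPRD2 from 61.6% ± 1.0 to 88.3% ± 1.8 and CPSF4 from 27.5% ± 3.3 to 46.7% ± 1.5. The list had 7 events over all and 8 adjusted over the list alone. Of 19 genes with published SRSF1-responsive events 7 were called, such as TEAD1 (12.8% ± 1.5 to 34.1% ± 4.2) and NUMB (19.7% ± 8.5 to 40.8% ± 1.3). The list had 7 events past limma over all and 10 adjusted over the list alone. A 267-nt coding exon of FN1, the stromal marker called of 3 measured, fell from 79.3% ± 0.17 to 36.1% ± 8.3 (SD, n = 2 and 3). The list had 1 event past limma over all and 5 adjusted over the list alone. Benjamini-Hochberg adjustment of the deposited p over a list alone left 0 events for IL-6 signalling, DNA damage, chromatin and stromal genes. It left 2 for cell cycle genes and 13 each for hnRNP and apoptosis genes.

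Targeting HNRNPL raised PSI at splice sites that were little used in control cells. An alternative 5' splice site of CD55, a complement regulator, at chromosome 1:207336819-207337250 rose from 1.17% ± 1.1 to 65.8% ± 6.1 (limma adjusted p = 0.00418). Sites in SH3BGRL at chromosome X:81202246-81237280 rose from 1.24% ± 0.35 to 65.7% ± 0.76 (limma adjusted p = 0.000914). PSI rose in LIN7C from 6.76% ± 0.71 to 66.9% ± 6.5 (limma adjusted p = 0.00651) and in the phosphatase gene INPP4A at chromosome 2:98582360-98587476 from 0.473% ± 0.58 to 58.9% ± 4.3 (limma adjusted p = 0.000558). Sites in TMEM178B and GALM, listed at 0% in all control libraries, reached 50.5% ± 10.5 and 50.3% ± 6.8 (SD, n = 3 each). Of 1047 called events in 731 genes 650 rose and 397 fell, so 62.1% rose (exact 95% interval 59.1 to 65%). The limma test called 94 up and 22 down, and 40 to 50 events with any 1 library left out.

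Alternative 3' splice sites rose in 121 events and fell in 44 (exact binomial adjusted p = 1.5e-08), alternative 5' splice sites in 82 and 40 (adjusted p = 0.000809), and single exons in 179 and 109 (adjusted p = 0.000227). Without the 10 points single exons were near an even split, 572 up and 525 down at p under 0.05, and past limma 11 rose and 3 fell. Retained introns rose in 21 and fell in 46 (adjusted p = 0.011), but without the 10 points 378 rose and 239 fell at p under 0.05, and past limma 3 rose and 0 fell. Exons tagged for nonsense-mediated decay rose in 68 called events and fell in 16 (adjusted p = 3.42e-08 against an even split), and the other called events rose in 582 and fell in 381. Those that rose included a 227-nt exon of the histone methyltransferase gene NSD2 (11% ± 1.7 to 38.3% ± 1.7, limma adjusted p = 0.0233) and TMEM219 (25.6% ± 5.6 to 73% ± 6.1, limma adjusted p = 0.0452). Among the largest decreases were LINC01138 (90.5% ± 0.64 to 41.9% ± 5.3, SD, n = 2 and 3) and NCAPG2 (47.6% ± 12.3 to 0% ± 0, SD, n = 3 and 2). UGGT2 (89.8% ± 2.8 to 48.6% ± 3.8), ELMOD1 (61.3% ± 16.8 to 20.8% ± 5.8) and NELFA (50.4% ± 5.3 to 13.9% ± 9.8, SD, n = 2 and 3) fell too.

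Genes with published HNRNPL-responsive events had 5 called members of 14, against 7.46% of other genes (Fisher's exact test, odds ratio 6.89, unadjusted p = 0.00265, adjusted p = 0.212). They were TJP1 (19.6% ± 2.8 to 54.1% ± 7.4), CD46 (48.3% ± 1.8 to 72.1% ± 6.0), FYN (87% ± 3.1 to 73.6% ± 5.1), BRD8 and CD44, with 0 events past limma over all and 1 adjusted over the list alone. With sgSRSF1, 6 of the 14 were called (Fisher's exact test, unadjusted p = 0.0396, adjusted p = 0.583), including BRD8 (58.7% ± 2.0 to 82.3% ± 2.4) and CD46 (67.9% ± 0.24 to 89.9% ± 0.2), with 13 events past limma over all and 15 adjusted over the list alone. B cell and plasma cell genes gave 5 of 25 (Fisher's exact test, unadjusted p = 0.0354, adjusted p = 0.583). NSD2, SLAMF7 (56.9% ± 2.9 to 78.2% ± 0.97) and LY9 (14.2% ± 0.97 to 30.2% ± 3.6) rose, with 2 events past limma over all and 10 adjusted over the list alone. Of 26 hnRNP genes 4 were called, such as the splicing factor gene HNRNPA2B1 (57.5% ± 1.1 to 39.1% ± 1.5) and HNRNPA3 (80.4% ± 0.99 to 65.3% ± 2.8), with 0 events over all and 8 adjusted over the list alone. SR protein genes gave 2 of 13, SRSF8 and SRSF10 (59.3% ± 0.66 to 71.7% ± 2.1), and core spliceosome genes 3 of 57, each with 0 events past limma over all and 0 adjusted over the list alone. Apoptosis genes gave 2 of 27, DNA damage genes 3 of 43, IL-6 signalling genes 1 of 30 and cell cycle genes 2 of 41. Elongation genes gave 3 of 26, secretory pathway genes 1 of 34, termination genes 1 of 23 and genes with published SRSF1-responsive events 4 of 20. Each of these lists had 0 events past limma over all and 0 adjusted over the list alone. Decay and turnover genes gave 3 of 27 and chromatin regulators 2 of 40, each with 1 event over all and 1 adjusted over the list alone. Called members included CASP8 from 28.9% ± 3.6 to 9.34% ± 3.3 and BPTF from 43.2% ± 1.5 to 75.1% ± 7.2. Further members were CENPE from 71% ± 8.7 to 42.9% ± 9.0 and FOXM1 from 66.3% ± 1.3 to 81.3% ± 2.5, then AKT1 from 91.3% ± 2.3 to 77.9% ± 5.4, XRN2 from 0.155% ± 0.13 to 12% ± 2.1 and CHEK2 from 84.6% ± 2.9 to 71.3% ± 4.8. Of the genes given with PSI but no limma value for sgHNRNPL, TMEM178B, GALM, LINC01138, NCAPG2, UGGT2, XRN2 and MFSD13A passed the adjusted limma test, and the others did not, with HNRNPL itself not tested.

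SRSF1 and HNRNPL shared 243 called events, of which 160 moved the same way (65.8%, exact 95% interval 59.5 to 71.8%, exact binomial adjusted p = 2.66e-06). The comparisons share their sgEGFP libraries, and unchanged groups simulated against shared controls gave 98.5% in the same direction. On average 32.3 events were called in both simulated comparisons, beside 233 observed among events with a value in every library. The simulation covered 64311 events with such values in either comparison, but the observed numbers cover the 48816 events in both. The simulated and observed counts and covariances are therefore not like for like. Among the 48816 events tested in both with a value in every library, 83 rose in both where independent lists give 9.78, and 72 fell in both where they give 11.3. The covariance of the differences was 7.42 against 5.7 in the simulation, 1.72 above it, but their correlation was 0.233 against 0.499, below it. The 3 control libraries could not be divided between the comparisons, so this excess is not free of the shared controls. MTERF4 fell with sgSRSF1 from 57.6% ± 7.0 to 13% ± 3.0 and rose with sgHNRNPL from 57.6% ± 7.0 to 93.6% ± 9.2. MFSD13A rose with both, from 4.08% ± 1.9 to 34% ± 3.9 and from 4.08% ± 1.9 to 32.2% ± 3.7. IL-6 in MM.1S shared 146 called events with sgSRSF1 (47.3% in the same direction, exact binomial adjusted p = 0.609 against an even split, but unadjusted p = 0.00226 against the 59.9% that the direction splits of the 2 tables give) and 61 with sgHNRNPL (45.9%, adjusted p = 0.609). IL15 (27.9% ± 4.0 to 54% ± 6.4) and ITGA6 (68.5% ± 4.8 to 92.6% ± 1.8) rose with sgSRSF1 where IL-6 lowered them, and XIAP fell with both.

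Across the 17 gene lists, 0 of 80 list tests passed an adjusted p of 0.05 (Fisher's exact test), and 6 had an unadjusted p under 0.05. With a call at 20 points, or with a background matched on the number of events per gene, 0 passed as well. T and NK cell markers had 0 of 17 members measured in MM.1S, and stromal and myeloid markers 3 of 18, of which FN1 was called.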

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

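The tests of explanations in this part were all chosen after the results were seen, and the test of a difference between the cell lines was applied to events already listed with p under 0.05 in both.

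In 9 events IL-6 moved PSI by at least 10 points in one direction in MM.1S and in the other direction in INA-6. The values below are the INA-6 difference minus the MM.1S difference, in points, with the limma interaction p adjusted over 638 events. These events were picked because they were called in opposite directions, so that all 9 pass the interaction test was all but fixed by the choice, as for the 3 events with sgPOU2AF1 below. A coding exon of HDAC7 fell by 14.8 in MM.1S and rose by 13.4 in INA-6 (difference 28.2, adjusted p = 1e-05). A TNRC6C exon fell by 27.1 and rose by 12 (39.1, adjusted p = 0.0025). PHYKPL exons at chromosome 5:178222355-178222580 and 5:178222852-178222934 fell by 25.4 and 20.5 in MM.1S and rose by 13.3 and 10.8 in INA-6 (38.7 and 31.3, adjusted p = 0.0003 and 0.0014). An INTS14 first-exon segment, listed at both chromosome 15:65610686-65610795 and 15:65610686-65611097 with the same values, fell by 17 and rose by 10 (27.0, adjusted p = 0.0074). A 3' splice site of BRD1 rose by 13.2 and fell by 14 (-27.1, adjusted p = 0.00032). A retained PINK1-AS interval, antisense to PINK1, rose by 24.5 and fell by 12 (-36.5, adjusted p = 0.00035). An exon of ENSG00000284906 rose by 10.4 and fell by 15.4 (-25.9, adjusted p = 0.0031).

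With sgPOU2AF1, 3 events differed in this way, with the limma interaction p adjusted over 608 events. PRDM15 fell by 18.1 in MM.1S and rose by 16.4 in INA-6 (34.6, adjusted p = 0.00046), PABIR2 fell by 12.3 and rose by 11.5 (23.8, adjusted p = 0.00079), and ZNF778 fell by 10.3 and rose by 13.6 (24.0, adjusted p = 0.0039). With sgELL2, 0 events were called in opposite directions, and limma placed 71 of 197 events past its adjusted interaction threshold in either direction. The number of events with an interaction was 288 of 638 for IL-6 and 207 of 608 for sgPOU2AF1. Of these, 112 and 91 moved the same way in both lines and differed in size on the logit scale, as did 34 of the 71 for sgELL2. Which provider made which library is not given in the sources used here, so a batch that parts treated from control libraries within a line stays open, while a shift common to both groups of a line cancels in these differences.

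The opposite directions of IL-6 and sgPOU2AF1 were weighed first. Retained introns and a lean of each table to one direction were argued against: without retained introns 90.5% of 42 events in MM.1S and 94.7% of 38 in INA-6 were opposite, and the direction splits of the tables by event type give 56.7 and 50.7%, beside 91.7 and 90.5% observed. The lower bounds of the observed shares, 80 and 77.4%, lie above an even split, but this restates the pattern and is no further test of chance calls. A programme common to both cell lines was tested across lines: INA-6 IL-6 events were opposite to MM.1S sgPOU2AF1 in 89.5% of 19, but MM.1S IL-6 events were opposite to INA-6 sgPOU2AF1 in only 18.4% of 38. Whether cells with sgPOU2AF1 respond less to IL-6 was not tested, since the libraries include no sgPOU2AF1 cells without IL-6, and provider batches stay open. The IL-6 and sgEGFP libraries are different libraries, identical in at most 0.264% of shared events. In INA-6 the same sgEGFP libraries served sgELL2, and all 11 events called with IL-6 and sgELL2 were opposite too. With no minimum difference, 27.5% of 356 such events moved the same way. For INA-6 a trait of these sgEGFP libraries therefore stays open.

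Retained introns with higher PSI with sgPOU2AF1 in INA-6 were weighed next. Controls low in unspliced RNA were argued against as the whole cause for introns listed with p under 0.05. Of these, 56.4% outside overlapping regions (interval 53.1 to 59.7%) and 58.1% within them (53 to 63.1%) rose with sgELL2 against the same sgEGFP libraries. With sgPOU2AF1 93.9 and 86.7% rose. Both sgELL2 intervals lie above an even split, so a part from such controls stays open. For called introns they stay open: in overlapping regions 73% of 37 rose with sgELL2 beside 76.1% with sgPOU2AF1, and outside them 58.6% of 29 (interval 38.9 to 76.5%) beside 79.6% (70.3 to 87.1%). Unspliced RNA or DNA left in the 3 sgPOU2AF1 libraries stays open, because introns over the p threshold are not listed, and in MM.1S 74.8% of listed introns outside overlapping regions rose with sgPOU2AF1. Of called introns in MM.1S 17 rose and 24 fell outside such regions, and 38 rose and 20 fell within them.

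Exon skipping with sgSRSF1 was weighed last. For controls high in exon inclusion, 37.8% of called single exons fell with sgHNRNPL against the same sgEGFP libraries, beside 72.9% with sgSRSF1. With no minimum difference, at p under 0.05, 572 rose and 525 fell with sgHNRNPL, beside 792 and 1890 with sgSRSF1. A rise of inclusion caused by sgHNRNPL itself could hide such a trait of the controls, so this explanation stays open. Of the 762 single exons past the adjusted limma test 76.6% fell, and that test called only 4 unchanged events in simulation. This argues against chance calls of single events. The test uses the same 6 libraries, so a shift common to many events in a library stays open. These values are in line with a loss of exon inclusion in the sgSRSF1 cells, as a hypothesis found and tested on the same data, and a provider batch stays open.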

How the results depend on the processing

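Adjustment of the deposited p, leaving out retained introns, dropping the minimum difference for shared events, and limits on missing values or overlap were chosen after seeing the data, and the other alternatives before the data were examined. In the order IL-6 in MM.1S and INA-6, sgPOU2AF1 in MM.1S and INA-6, sgELL2 in MM.1S and INA-6, sgSRSF1 and sgHNRNPL, a deposited p under 0.01 left 307, 171, 101, 225, 64, 79, 1558 and 358 called events, and 20 points left 116, 85, 66, 117, 48, 74, 1168 and 273. Benjamini-Hochberg adjustment of the deposited p left 0 in the first 6 comparisons, 178 for sgSRSF1 and 0 for sgHNRNPL, where unadjusted p under 0.05 gave 5776, 4729, 4151, 7256, 2823, 3595, 9503 and 4241 events of any size, and limma called 800, 568, 420, 734, 306, 361, 2058 and 116. Counting genes gave 1879 for sgSRSF1. With no minimum difference limma called 4737, 3868, 3322, 5715, 2220, 2812, 4116 and 189 events, since smaller changes are then counted.

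Leaving out 1 library, whichever of the 6 it was, gave 748 to 999 limma calls for sgSRSF1 and 40 to 50 for sgHNRNPL, with fewer libraries in the test. The other limma counts were 773 to 809 and 515 to 552 for IL-6, 402 to 419 and 679 to 721 for sgPOU2AF1, and 252 to 272 and 322 to 339 for sgELL2, but these 6 tables list events already under 0.05 with all libraries, so these counts say nothing about stability. Clipping at 5 and 95% gave 2678 and 131 limma calls for sgSRSF1 and sgHNRNPL, and untransformed PSI 2094 and 119. Of 403 named called events, 368 stayed at or above 10 points with any 1 library left out. Their direction could not reverse, because the groups of called events do not overlap.

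At 20 points in both comparisons few events are left to test: 100% of 2 moved the same way for IL-6 in both lines (exact binomial adjusted p = 1), 100% of 2 for sgPOU2AF1 in both lines (adjusted p = 1), 0% of 4 for IL-6 and sgPOU2AF1 in INA-6 (exact adjusted p = 0.5), and 66.7% of 3 for IL-6 and sgPOU2AF1 in MM.1S, a reversal (exact adjusted p = 1) in which 2 of the 3 are 1 TTBK2 site under 2 coordinate pairs. In MM.1S this last share was 7.32 to 19% under the other alternatives, with adjusted p from 4.54e-103 to 1.22e-05. In INA-6 the share for IL-6 and sgPOU2AF1 was 5.26 to 26.7% under them (exact binomial adjusted p from 4.87e-41 to 0.000245). With 1 event per gene the same-direction share for sgPOU2AF1 across lines was 78.6% of 14 (exact binomial adjusted p = 0.0833). For sgELL2 across lines it was 100% of 6, ELL2 itself among them (exact binomial adjusted p = 0.0536). For sgPOU2AF1 and sgELL2 in MM.1S it was 100% of 5 (exact binomial adjusted p = 0.0833), also with retained introns left out. Each of these shares rests on fewer events than the main one. Matching by gene and type gave 25% of 16 for IL-6 and sgELL2 in INA-6 (adjusted p = 0.102), where the cause was not tested. Of the values for whole comparisons, 140 kept their side of the threshold or stayed within 1.5 times (the counts without 1 library in the 6 tables of selected events included), 45 counts moved further, 8 lost significance and 1 reversed.

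No paired analysis was possible because the columns carry no replicate number, so the replicate block was not run. Minimums of 20 or 30 reads were not run, since reads are not listed. Depth is unknown, so its limit on single PSI values could not be measured.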

Other observations

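All tests in this part other than the splits of libraries were chosen after the results were seen, and what the splits would show was also written down after.

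Targeting HNRNPL raised PSI at splice sites that control cells hardly used. Of 650 events that rose, 111 in 70 genes (17.1%) had a control mean under 5%, with a median rise of 18.5 points. Of these 74 were alternative 3' or 5' splice sites, such as those in CD55, SH3BGRL and INPP4A, and 53 passed limma. With sgSRSF1 the number was 89 of 1067 (8.34%), in 77 genes, with 69 past limma (Fisher's exact test, odds ratio 2.26, p = 1e-07; events of one gene are not independent). The shares were 5.76 and 3.69% for IL-6 in MM.1S and INA-6, 1.7 and 2.59% for sgPOU2AF1, and 6.71 and 0.995% for sgELL2.

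Some events changed in many comparisons. Comparisons with the same sgEGFP libraries, sgPOU2AF1 and sgELL2 in INA-6 and sgSRSF1 and sgHNRNPL, share calls even with no change, so the number of such events has no meaning by itself. Called in 5 comparisons, in each case with such a pair among them, were a BRD1 3' splice site, an ENTPD1-AS1 site listed with 2 coordinate pairs, a PABIR2 exon and an ST3GAL6 exon. The BRD1 site differed by 13.2 and -14 points with IL-6 in MM.1S and INA-6, by 13 and 12.2 with sgPOU2AF1 and sgELL2 in INA-6 and by 21.7 with sgHNRNPL. The ST3GAL6 exon fell by 15.2 with IL-6 in MM.1S, by 14.6 and 18 with sgPOU2AF1 in MM.1S and INA-6 and by 14.4 with sgSRSF1, and rose by 19.1 with sgHNRNPL. An IGFLR1 exon run was lower in both lines with sgPOU2AF1 and with sgELL2 (-17.9, -13.9, -21.0 and -12.3 points).

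Of 16 further pairs of comparisons, 4 had an uneven split of directions after adjustment over the 16 (exact binomial). IL-6 in MM.1S and sgPOU2AF1 in INA-6 moved 81.6% of 38 shared events the same way (adjusted p = 0.0019), IL-6 in INA-6 and sgPOU2AF1 in MM.1S 10.5% of 19 (adjusted p = 0.0039), sgPOU2AF1 in INA-6 and sgELL2 in MM.1S 91.7% of 12 (adjusted p = 0.025), and sgPOU2AF1 in INA-6 and sgSRSF1 72.9% of 59 (adjusted p = 0.0039).

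The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave the most limma calls in each comparison, 1 of 10 splits: 800, 568, 420, 734, 306 and 361 calls for IL-6, sgPOU2AF1 and sgELL2 in MM.1S and INA-6 in turn, with 0 in the highest other split of each, 2058 for sgSRSF1 with 1, and 116 for sgHNRNPL with 2. In the first 6 the events had been selected on the real split.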
